A study of Mus musculus with 4 samples.

How the data were processed

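Whole-lung RNA from mice of the C57BL/6 family and a control genotype was measured by RNA sequencing in 4 libraries. Per the labels, 2 libraries came from normoxic mice and 2 from mice given Sugen, an inhibitor of VEGF receptors, together with hypoxia. The sex entries of the labels list 3 females for normoxic replicate 1, 1 female and 2 males for normoxic replicate 2, and 2 males for each Sugen-hypoxia replicate, so each library was taken as a pool of that many animals. Replicate numbers follow the order of the records and pair no samples. The genotype arm with KCNK3 mutations that the series' design text names was not analysed here. The source label gives lung while the extraction text names kidneys, and the tissue was therefore checked on marker genes.

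The deposited files hold raw read counts per gene, 1 file per library, with the authors' counts for unstranded reads and for each strand in separate columns. Alignment with STAR 2.5.1b to GRCm38.p4 and counting with HTSeq are named in the submitters' processing notes, and the layout of the files is that of STAR's own gene counts. The gene annotation and the library kit's strandedness are not given in the sources used here. Counts in the column for reads antisense to read 1 were 20.9 to 24.9 times those in the sense column, so that column was used and the unstranded column was kept as an alternative. Each file lists 47729 genes, of which 47310 matched the GENCODE mouse release 21 annotation of GRCm38, the source of the symbols, gene types and coordinates. Where more than 1 identifier carried a symbol, which was so for 67 symbols, the one with the highest total was taken. The summary rows for unmapped reads, multimapping reads, reads without a feature and ambiguous reads stayed out of library sizes and tests. They held 6.45 to 7.55%, 4.5 to 4.54%, 7.73 to 9.98% and 1.1 to 1.13% of all reads. Reads that map to more than 1 place were not counted per gene, so genes with near-identical copies are undercounted. The mitochondrial gene mt-Co2 was at 0.292 CPM (gene counts scaled to 1e6 per library) in normoxic libraries against 6513 for mt-Co1. Whether its low count comes from such reads was not tested.

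Gene counts summed to 67.1 and 58.2 M in normoxic replicates 1 and 2 and to 57.3 and 65.3 M in Sugen-hypoxia replicates 1 and 2. At this depth 1 CPM stands for at least 57.3 reads, so that for most named genes the spread between pools, not counting error, limited the precision.

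Genes were kept by edgeR's filterByExpr with the 2 groups, which left 18783, and library sizes were scaled by TMM factors. Differences between groups were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 4 libraries with group as the only term, and adjusted by Benjamini-Hochberg at 0.05. Log2 fold changes are Sugen-hypoxia over normoxia, with standard errors derived from the F statistic. All tests were two-sided. CPM values are given as mean ± SD over the 2 libraries of a group. The test was tried on simulated data for this comparison with 18783 genes and 5 draws in which 200 genes were changed. It recovered 32.8% of genes changed 1.5-fold, 69% of those changed 2-fold and 85.8% of those changed 4-fold, and 13.5% of its calls were false, above the nominal 0.05 share.

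A total of 42 gene lists fixed before the data were examined were tested. They covered glycolysis and HIF targets, aryl hydrocarbon receptor targets, extracellular matrix, smooth muscle, pericytes and fibroblasts, endothelium, VEGF-responsive genes, BMP and TGF-beta signalling, heritable pulmonary hypertension, potassium channels, vasoactive pathways, p53, unfolded protein response, immediate early and heat shock genes, glucocorticoid response, interferon response, type 2 mediators, cell cycle, clock, lipid synthesis, and nuclear and mitochondrial respiration genes. Cell type lists covered type 1 and type 2 alveolar, club, ciliated, mesothelial, T and NK, B, neutrophil, mast and basophil, monocyte and dendritic, alveolar macrophage, erythroid, cardiac, skeletal muscle, fat, thymus, kidney and lung markers, and sex was covered by Y-linked and X-inactivation genes. Of 969 members typed, 967 were found in the files. Lists with at least 5 tested members, 40 in all, entered camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Beside it stand camera with an estimated correlation, limma's fry, and the counts of members past the threshold when adjusted over all genes and when adjusted over the list alone. Of the 21 lists that camera called, 0 kept the call with an estimated correlation and 0 passed fry's test for a balance of members in 1 direction, while 35 of the 40 lists passed fry's mixed test, which asks whether members change in either direction. With 2 residual degrees of freedom the estimated correlations are themselves poorly determined.

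Genes were named by a rule fixed before the data were examined. It took Kcnk3 always, the 12 largest rises and 12 largest falls among autosomal protein-coding genes past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 3 passing members of each list (or the 2 of highest CPM where none passed), Xist and the Y-linked genes, and any member of the pulmonary hypertension and potassium channel lists. Clone-type symbols and variable segments of immune receptors were skipped in the lists of largest changes. A few further genes are named outside this rule, among them Sftpc, Umod and Gatm for the tissue check and mt-Co2 for read mapping. Lists written after the data were seen are marked as such.

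The alternatives tried were RLE and upper-quartile factors, no scaling beyond library size, no filter, a filter on a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the unstranded counts, each library left out, the male fraction of the pool as a covariate, autosomal genes alone, haemoglobin and immunoglobulin genes left out, a test against a 1.5-fold change, and lists without shared members. Duplicate deposition was checked by a chi-square test over gene counts. The statistic per degree of freedom was 12.9 between the normoxic libraries and 61.4 between the Sugen-hypoxia libraries, where sampling noise alone gives about 1, and each library was counted once. Figures were drawn with matplotlib.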

Results

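Gene expression was measured in lungs of control-genotype mice kept in normoxia or given Sugen and hypoxia together, a combination used in rodents to produce pulmonary hypertension. The series is about mutations of KCNK3, the gene of a two-pore-domain potassium channel. The samples analysed here were of the control genotype, so the comparison is of lungs with the gene intact. Each group held 2 libraries of pooled animals, 6 normoxic and 4 treated mice in all, with 57.3 to 67.1 M gene counts per library (M, 1e6). The treated pools were all male and the normoxic pools partly or wholly female, and Sugen was not given apart from hypoxia, so treatment was tested with sex on the same side.

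The libraries carried the profile of lung. The surfactant gene Sftpc was at 11230 to 12370 CPM in the 4 libraries, and the median of the 15 lung identity genes was 764 to 972 CPM. The median of the 18 kidney markers was 0.018 to 0.0832 CPM, with Umod, the main urinary protein, at 0 CPM in 3 of 4 libraries. Lrp2, an endocytic receptor of several epithelia, was the highest of them at 104 to 175 CPM, and Cdh16, a cadherin, and Gatm, a creatine synthesis enzyme, were at 8.92 to 11.4 and 5.65 to 13.9 CPM. Of the kidney list, 8 members passed the expression filter and 0 changed (0 adjusted over the list alone; camera adjusted p = 0.361).

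Sex-linked genes followed the pool labels. Xist, the X-inactivation RNA, was at 494 CPM in the all-female normoxic pool, 149 CPM in the mixed normoxic pool and 0.505 and 0.512 CPM in the all-male treated pools. The mixed pool held 0.3 of the all-female level, against a labelled female share of 0.333. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty stood in the mixed pool at 0.53, 0.673, 0.69 and 0.636 of the treated mean, against a labelled male share of 0.667. None of the 4 passed the test (0 adjusted over the list alone), because the normoxic pools lay far apart. On the X-inactivation list Xist fell (1 of 8 members; 5 adjusted over the list alone; camera adjusted p = 0.00698, adjusted p = 0.711 with an estimated correlation).

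Between Sugen-hypoxia and normoxia 2163 of 18783 genes differed in edgeR's quasi-likelihood test, 1035 higher and 1128 lower. With the male fraction of the pool as a covariate, which leaves 1 residual degree of freedom, 11 genes passed, 7 of them among the 2163. The 11 included the 4 Y-linked genes, which were not among the 2163, and 1 gene of the X-inactivation list, all called as lower. Among the 12 largest rises of autosomal protein-coding genes with a mean of at least 1 CPM were those in targets of the aryl hydrocarbon receptor, Cyp1a1, Cyp1b1 and Ahrr, in the macrophage genes Arg1 and Mmp12, and in the basement membrane gene Lama1. Among the 12 largest falls were those in Ankrd63, an ankyrin repeat gene of little known function, in the monocarboxylate transporter Slc5a12, in the retinoic acid hydroxylase Cyp26b1 and in the Notch ligand Dll4. Camera called the matrix and smooth muscle lists as higher and the ciliated, T and NK, B cell and neutrophil lists as lower, and 0 of its 21 list calls were kept with an estimated correlation. A total of 250 genes rose and 324 fell at least 2-fold, and 93 rose and 60 fell at least 4-fold.

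The size of the list depended on single libraries. Without normoxic replicate 1 the spread came from the treated pair alone and 25 genes passed, and without normoxic replicate 2 it was 113, while without treated replicate 1 or 2 the counts were 5101 and 4777. Of 111 named genes past the threshold, 13 kept the call without normoxic replicate 1 and 28 without normoxic replicate 2, while 111 kept it without either treated replicate. P-values here measure only the spread between these 4 pools.

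Several of the leading genes held in every fit with 1 library left out. They were 25 in number and included Ankrd63, Cyp1b1, Dll4, Lama1, Ighd, Aspn, Slc5a12, Rgs5, Ahrr, Ednrb, Cdkn1a and Cyp1a1. Xist was also among the 25 and follows the sex of the pools, so holding in every fit does not separate treatment from sex. Cyp1b1 (ENSMUSG00000024087, GRCm38 chromosome 17, 79701537 to 79715061) went from 16.1 ± 2.14 to 1419 ± 195 CPM (SD, n = 2), a log2 fold change of 6.46 ± 0.17 (SE) with adjusted p = 0.000488. Ankrd63 (ENSMUSG00000078137, chromosome 2, 118699103 to 118703963) fell from 25.5 ± 1 to 0.548 ± 0.0599 CPM, a change of -5.53 ± 0.13 with adjusted p = 0.000488. Dll4 (ENSMUSG00000027314, chromosome 2, 119325784 to 119335962), a Notch ligand of sprouting endothelium, fell 6.08-fold from 80.7 ± 4.53 to 13.3 ± 0.502 CPM. Lama1 (ENSMUSG00000032796, chromosome 17, 67697259 to 67822647) rose 15.7-fold. Among the other large changes, Ptx3, Olfr78, Mmp13, Chodl and Duox1 rose from means under 0.5 CPM, with Duox1 at 0 in normoxic replicate 1. The log2 fold changes of these genes other than Ptx3 moved with single libraries. That of Duox1 went from 5.99 to 4.64 without treated replicate 2. Without normoxic replicate 2 it was 10.62, but the normoxic count left is then 0 and does not determine the size. That of Olfr78 went from 4.24 to 5.49 without normoxic replicate 2 and 3.54 without normoxic replicate 1. Without treated replicate 2 Chodl went from 6.09 to 5.09 and Mmp13, which rose 16-fold with all libraries, to 2.85. Olfm2, Entpd8, Doc2b, Rbfox3, Acod1, S1pr5 and Klrc1 fell by 2.23 to 3.42 on the log2 scale. Doc2b, at 8.57 and 2.24 CPM in the normoxic pools, went from -3.10 to -1.81 without normoxic replicate 1, and Cyp26b1 from -2.78 to -2.15. Cyp26b1 was at 238 CPM in the all-female and 115 CPM in the mixed normoxic pool. The all-male treated pools were at 0.578 and 0.683 CPM for Doc2b and 30.2 and 21.4 CPM for Cyp26b1. In both genes the mixed pool lay between the all-female and the all-male pools, so a part of pool sex stays open.

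**Figure D1:**
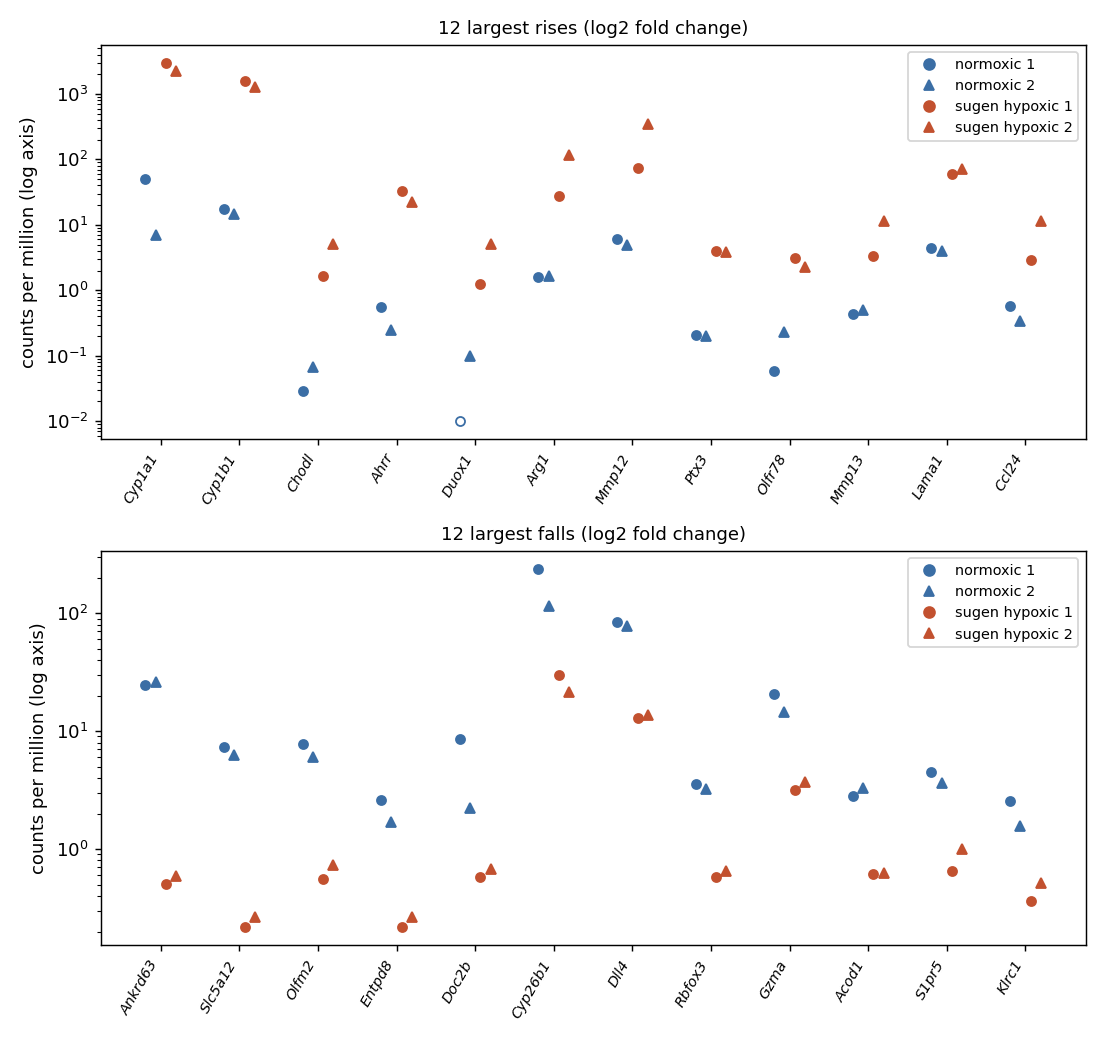
CPM on a log axis in each of the 4 libraries for the genes with the 12 largest rises (top) and 12 largest falls (bottom) in log2 fold change among autosomal protein-coding genes past the threshold with a mean of at least 1 CPM. Blue symbols are the normoxic and orange symbols the Sugen-hypoxia libraries, with circles for replicate 1 and triangles for replicate 2, and an open symbol marks a library with 0 counts, drawn at 0.01. The treated pools lie close together for Cyp1b1 and Lama1 but are 4.23-fold apart for Arg1 and 4.67-fold apart for Mmp12.

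Of 9 measured targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor that induces drug-metabolising enzymes, 6 rose, 0 fell and 3 did not pass, with the same 6 adjusted over the list alone. Cyp1a1 rose from 28.8 ± 30.6 to 2630 ± 552 CPM, where the normoxic pools themselves differed (50.4 and 7.12 CPM). Without normoxic replicate 1 its log2 fold change went from 6.51 to 8.53, and without normoxic replicate 2 to 5.70. Ahrr, the receptor's repressor, rose 66.9-fold, and its log2 fold change went from 6.06 to 6.78 without normoxic replicate 1. Camera gave adjusted p = 8.34e-05 for the list, and adjusted p = 0.613 with an estimated correlation. With normoxic replicate 1 or 2 left out, 3 and 4 members passed, among them the 3 named here.

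Extracellular matrix genes had a median log2 fold change of 0.74. Of 42 members 22 rose and 1 fell, or 32 and 1 adjusted over the list alone. Eln, the gene of elastin, rose from 203 ± 10.2 to 1522 ± 362 CPM, a log2 fold change of 2.90 ± 0.18, and Tnc, tenascin C, rose by 2.12 ± 0.40. Mmp12, a macrophage elastase, rose by 5.25 ± 0.79, with 74.8 CPM in treated replicate 1 and 349 in replicate 2. Without treated replicate 2 its log2 fold change was 3.75 and that of Tnc 1.40. The list passed camera (adjusted p = 1.66e-13; adjusted p = 0.613 with an estimated correlation). Leaving out normoxic replicate 1 or 2 left 1 and 4 members higher.

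Contractile genes of smooth muscle rose by smaller amounts, 9 of 22 with 0 falls (11 and 0 adjusted over the list alone). Tagln rose 1.75-fold to 230 ± 0.717 CPM, Myl9 by 0.76 and Cald1 by 0.73 on the log2 scale. The list had camera adjusted p = 3.4e-05, and adjusted p = 0.604 with an estimated correlation. Among 24 pericyte and fibroblast markers, 7 rose and 2 fell (7 and 3 adjusted over the list alone), led by Rgs5, a pericyte regulator of G-protein signalling, at 5.9-fold, Aspn at 3.26-fold and Mfap4 at 2.74-fold. Its camera adjusted p = 0.0354 became adjusted p = 0.613 with an estimated correlation. Leaving out normoxic replicate 1 or 2 left 0 and 0 smooth muscle genes and 2 and 2 pericyte and fibroblast genes. The pericyte and fibroblast list had adjusted p = 0.0519 without normoxic replicate 1 and 0.0815 without treated replicate 1.

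Endothelial genes moved in both directions. Of 34 markers 8 rose and 9 fell (12 and 10 adjusted over the list alone), and camera gave adjusted p = 0.982. The capillary genes Fibin, Ednrb and Plvap fell 3.83-fold, 3.45-fold and 2.47-fold, and Sox17, a transcription factor of arterial endothelium, rose 1.88-fold. The VEGF-responsive and tip cell list was also split, with 9 of 21 higher and 3 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.00528, adjusted p = 0.613 with an estimated correlation). Within it Vegfc, a ligand of VEGF receptors, rose from 17.4 ± 1.91 to 92.1 ± 21.3 CPM, while Dll4 and Esm1, both known to be induced by VEGF, fell 6.08-fold and 3.24-fold. With normoxic replicate 1 or 2 left out, 0 and 0 endothelial genes passed as higher and 1 and 3 as lower. The endothelial markers list had adjusted p = 0.0405, as higher, without treated replicate 2, and a median of -0.07 (12 higher, 16 lower) without treated replicate 1. Of the VEGF-responsive and tip cell list 0 passed as higher and 1 as lower without normoxic replicate 1, and 1 and 1 without normoxic replicate 2.

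Genes of BMP and TGF-beta signalling were likewise divided, 11 of 39 higher and 6 lower (14 and 8 adjusted over the list alone; camera adjusted p = 0.0777). Grem1, a secreted BMP antagonist, rose 8.88-fold from 0.589 ± 0.0777 CPM, a log2 fold change of 3.15 that went to 2.45 without treated replicate 2. Smad6, an inhibitor of BMP signalling that BMP itself induces, fell 2.67-fold to 79.2 ± 20.6 CPM, and the transcription factor Hey1 fell 2.35-fold. No member passed without normoxic replicate 1 or without normoxic replicate 2, and the BMP and TGF-beta signalling list had adjusted p = 0.0161 without treated replicate 2 and 0.429 without treated replicate 1.

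Kcnk3 (ENSMUSG00000049265, GRCm38 chromosome 5, 30588170 to 30625271, plus strand), the gene of the series' title, was at 64.4 ± 0.122 CPM in normoxia and 50.3 ± 6.19 CPM after treatment. Its log2 fold change of -0.36 ± 0.09 had adjusted p = 0.0642 and did not pass. It did pass with DESeq2 (adjusted p = 0.0171), no expression filter (0.00822), upper-quartile factors (0.0458) or library size only (0.0322). With RLE factors, a mean CPM filter, limma-voom or unstranded counts it did not pass (0.0581 to 0.0699). Nor did it with autosomal genes alone (0.0627) or without haemoglobin and immunoglobulin genes (0.0546). The male fraction as a covariate left its log2 fold change at -0.36, with adjusted p = 0.638. With a library left out, adjusted p ran from 0.299 without normoxic replicate 1 and 0.298 without normoxic replicate 2 to 0.0164 without treated replicate 2 and 6.97e-05 without treated replicate 1.

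Of 18 measured genes of heritable pulmonary hypertension, 1 rose and 6 fell (3 and 8 adjusted over the list alone). Bmpr2, the BMP receptor most often mutated in the disease, fell from 1145 ± 42.5 to 766 ± 34.6 CPM, a log2 change of -0.58 ± 0.08 with adjusted p = 0.0146. Eng, a co-receptor, fell 1.65-fold, Abcc8 fell 3.02-fold from a low level of 1.65 CPM, and Kcnk2, Tbx4 and Atp13a3 fell by 0.45, 0.36 and 0.30 on the log2 scale. Sox17 rose. The values for Acvrl1 and Aqp1, 0.50 and 0.52, did not pass. The list had camera adjusted p = 0.0152, and adjusted p = 0.665 with an estimated correlation. None of its members passed without normoxic replicate 1 or without normoxic replicate 2, and the list of heritable pulmonary hypertension genes had adjusted p = 0.12 without treated replicate 2.

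**Figure D2:**
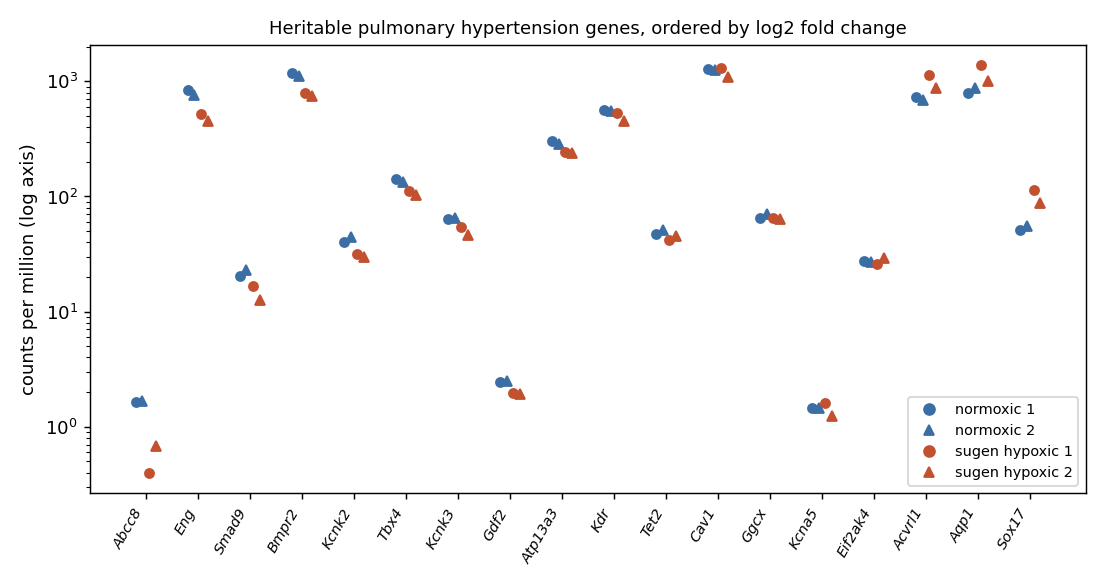
CPM on a log axis in each of the 4 libraries for the 18 measured heritable pulmonary hypertension genes, ordered from the lowest to the highest log2 fold change. Blue symbols are normoxic and orange symbols Sugen-hypoxia libraries, with circles for replicate 1 and triangles for replicate 2. Both treated pools lie below both normoxic pools for Bmpr2, Eng and Kcnk3 and above them for Sox17.

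Potassium channel genes changed in either direction, 5 of 27 higher and 3 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.613). The balance turned to 3 higher and 5 lower with upper-quartile factors and likewise with library size alone. Kcnn3, a calcium-activated channel, rose from 20.3 ± 0.694 to 36.2 ± 2.16 CPM, and Kcne4, Kcne2 and Kcnq1 rose by 0.52, 0.44 and 0.30 on the log2 scale. Kcnq5 fell by 0.85, Kcnk5 by 0.48 and Kcnk2 by 0.45. Among 36 genes of vasoactive pathways, 6 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.723). Htr2a, a serotonin receptor, rose 2.93-fold and Ednrb, an endothelin receptor, fell. The median of the vasoactive list was 0.01 and turned to -0.04 with upper-quartile factors and -0.06 with library size alone. The vasoactive pathways list had adjusted p = 0.0294, as higher, without treated replicate 2, and a median of -0.13 (9 higher, 13 lower) without treated replicate 1. No potassium channel gene passed without normoxic replicate 1 or without normoxic replicate 2.

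Genes of glycolysis and HIF, the hypoxia-inducible factor, rose in 14 of 38 cases and fell in 2 (24 and 3 adjusted over the list alone). Egln3, an oxygen sensor that HIF induces, rose 2.78-fold and Ndrg1 1.98-fold. Hilpda, a lipid droplet protein also known as a HIF target, went the other way and fell from 51 ± 1.13 to 12.7 ± 3.19 CPM. The list had camera adjusted p = 1.13e-06, and adjusted p = 0.604 with an estimated correlation. With normoxic replicate 1 or 2 left out, 0 members passed as higher.

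Genes of the list for senescence and p53, a stress-responsive transcription factor, rose in 8 of 15 cases (8 higher and 1 lower adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose from 84.2 ± 11.2 to 205 ± 2.1 CPM, the X-linked Eda2r by 1.47 and Gdf15 by 2.02 on the log2 scale. Camera gave adjusted p = 7.08e-05, and adjusted p = 0.613 with an estimated correlation. Immediate early and heat shock genes rose in 7 of 29 cases and fell in 0 (10 and 1 adjusted over the list alone; camera adjusted p = 7.05e-05, adjusted p = 0.613 with an estimated correlation), with Egr2, Egr1 and Dnajb1 higher by 2.02, 1.79 and 1.01. Egr1 was at 698 CPM in treated replicate 1 and 291 in replicate 2, and its log2 fold change was 1.03 without treated replicate 1. Of 18 glucocorticoid-responsive genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.121), including the metallothionein Mt2 at 1.66 and Sult1a1 at -0.89. None of 22 unfolded protein response genes passed (0 adjusted over the list alone), though the list's median of 0.17 had camera adjusted p = 0.0108, and adjusted p = 0.613 with an estimated correlation. The chaperone genes Hsp90b1 and Calr were at 0.17 and 0.23. Leaving out normoxic replicate 1 or 2 left 1 and 1 p53 targets and 0 and 3 immediate early and heat shock genes. Without treated replicate 2, the list of glucocorticoid-responsive genes had adjusted p = 0.00102, while its median of 0.27 turned to -0.03 (7 higher, 6 lower) without treated replicate 1, and the unfolded protein response list had 0.0536 without treated replicate 2.

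T and NK cell genes had a median log2 fold change of -1.16. Of 30 members 24 fell and 0 rose (28 and 0 adjusted over the list alone; camera adjusted p = 2.65e-15, adjusted p = 0.604 with an estimated correlation). The cytotoxic granule genes Gzma and Gzmb fell by 2.35 and 2.01 on the log2 scale and the NK receptor gene Ncr1 by 2.09. Gzma went from 17.5 ± 4.25 to 3.42 ± 0.404 CPM. B and plasma cell genes fell in 13 of 27 cases with 0 rises (15 and 0 adjusted over the list alone; camera adjusted p = 1.05e-07, adjusted p = 0.613 with an estimated correlation), led by Pax5, Ighd and Cr2 at -1.59, -1.57 and -1.47. The treated pools differed in B and plasma cell genes, with 6 higher and 16 lower without treated replicate 1 and 0 higher and 21 lower without treated replicate 2. Neutrophil genes fell in 9 of 16 cases (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 3.4e-05, adjusted p = 0.613 with an estimated correlation). Ngp, a granule protein gene, fell 3.58-fold and Il1b 2.7-fold, while Gm5483, of a family of near-identical genes whose reads are hard to assign, was at -1.44. Without normoxic replicate 1 or 2, 0 and 4 T and NK genes, 1 and 5 B cell genes and 0 and 3 neutrophil genes passed as lower.

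Basophil and mast cell genes fell in 2 of 12 cases, Fcer1a and Mcpt8, both near 1 CPM in normoxia, where Mcpt8 went from -2.21 to -3.02 without treated replicate 2, and Kit, which other lung cells also express, rose 1.69-fold (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.131). Of the 10 thymus markers 3 were measured and 0 changed (1 lower adjusted over the list alone), too few for camera.

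Macrophage genes went up in part. Among 26 alveolar macrophage markers 4 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00511, adjusted p = 0.711 with an estimated correlation). Chil3, a chitinase-like protein, rose from 628 ± 62.1 to 2999 ± 1982 CPM, and the protease gene Ctsk rose 5.83-fold. Among 28 type 2 and cytokine mediators 7 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.746 with an estimated correlation). Arg1 rose 43.5-fold, and the chemokine genes Ccl24 and Cxcl1 rose by 3.94 and 2.37 on the log2 scale. Treated replicate 2 stood above replicate 1 in these genes, 4.23-fold for Arg1, 3.96-fold for Ccl24, 2.99-fold for Ctsk and 2.75-fold for Chil3. Without treated replicate 2 their log2 fold changes were 4.06 for Arg1, 2.63 for Ccl24, 1.55 for Ctsk and 1.35 for Chil3. That of Cxcl1 was 3.07 without normoxic replicate 2. Without treated replicate 2 the list of type 2 and cytokine mediators had adjusted p = 0.523. Monocyte, interstitial macrophage and dendritic genes were mixed, 5 of 32 higher and 5 lower (10 and 9 adjusted over the list alone; camera adjusted p = 0.7). Siglech, a plasmacytoid dendritic cell gene, fell 4.08-fold, Treml4 fell 3.21-fold and Ms4a7 rose 2.34-fold. None of the alveolar macrophage and type 2 genes passed as higher without normoxic replicate 1 or without normoxic replicate 2.

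All 24 ciliated cell genes fell (24 adjusted over the list alone), with a median of -0.72. The axonemal genes Hydin, Dnah9 and Dnah12 fell by 1.14, 1.05 and 1.02 on the log2 scale, Hydin from 52.5 ± 2.35 to 23.9 ± 4.14 CPM. Camera gave adjusted p = 2.65e-15, and adjusted p = 0.604 with an estimated correlation. None of the 24 passed without normoxic replicate 1 or without normoxic replicate 2, and 24 passed without either treated replicate. Club and secretory cell genes fell in 3 of 16 cases (3 adjusted over the list alone; camera adjusted p = 0.0545), among them Cyp2f2 and Scgb3a2 at -0.61 and -0.59, and the list's mean was 0.15 against a median of -0.12. The club and secretory cell markers list had adjusted p = 0.0371 without normoxic replicate 2 and 4.33e-08 without treated replicate 2, but its median turned to 0.07 (5 higher, 5 lower) without treated replicate 1 and 0.01 without normoxic replicate 1.

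Alveolar type 1 markers fell in 3 of 17 cases and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.742 with an estimated correlation). Igfbp2 rose 2.24-fold, Rtkn2 fell by 0.51 and Sec14l3 by 0.40. The alveolar type 1 cell markers call ended without normoxic replicate 2 (adjusted p = 0.19), without treated replicate 2 (0.134) and with RLE size factors (0.0531). Among 18 type 2 cell markers 2 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.314). They were Fasn at 0.64, the X-linked S100g at 0.62 and Etv5 at -0.33. Of the 15 lung identity genes 3 fell (5 adjusted over the list alone; camera adjusted p = 0.0514). These were Cyp2f2, Scgb3a2 and Rtkn2, already counted among the club and type 1 cell genes. Sec14l3 likewise stands on both the type 1 and the ciliated list. Of 10 mesothelial markers Muc16 and Lrrn4 fell, at -0.75 and -0.36 (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0917). With a library left out the alveolar type 2 cell markers list had adjusted p = 0.0477, as higher, without treated replicate 1. The lung identity markers list had 0.00845 without treated replicate 1 and 0.00525 without treated replicate 2, and the mesothelial markers list 0.0169 without the latter.

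None of 36 cell cycle genes passed (0 adjusted over the list alone). Their median of 0.61 had camera adjusted p = 0.00856, and adjusted p = 0.769 with an estimated correlation, but it stood on treated replicate 2, where Mki67 was at 64 CPM against 23.7 in treated replicate 1 and 23.4 and 31.2 in the normoxic pools. Without treated replicate 2 the cell cycle list pointed lower, with adjusted p = 0.523, and without normoxic replicate 1 adjusted p was 0.153. Clock genes changed in 4 of 21 cases, 2 higher and 2 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.0855). This split moved with scaling, to 0 higher and 4 lower with library size alone and 1 and 2 with upper-quartile factors. Npas2, a partner of the clock activator, rose 2.5-fold, and Hlf and Usp2 fell by 1.10 and 0.96. Of 40 interferon response genes 1 passed as higher and 2 as lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.13), with Ddx58 at 0.27, Bst2 at -0.30 and Oas3 at -1.78. The circadian clock list had adjusted p = 6.82e-05 without treated replicate 1 and 0.0468 without treated replicate 2, and the interferon response list 9.49e-05 without treated replicate 2, all as lower. Without treated replicate 1 the interferon median turned to 0.02, with 13 genes higher and 8 lower.

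Of 30 cholesterol and lipid synthesis genes 3 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.856). Me1 rose by 0.70, and the acetyl-CoA enzymes Acacb and Acss2 fell by 0.82 and 0.68 on the log2 scale. None of 12 mitochondrially encoded genes passed (0 adjusted over the list alone; camera adjusted p = 0.723), with mt-Co1 at 6513 ± 246 and 6494 ± 141 CPM. None of 30 nuclear genes of oxidative phosphorylation passed (0 adjusted over the list alone), with Atp5b and Atp5a1 at 0.01 and -0.02. That list's median of 0.07 had camera adjusted p = 0.048, and adjusted p = 0.742 with an estimated correlation. The nuclear oxidative phosphorylation call ended without normoxic replicate 1 (adjusted p = 0.147), without treated replicate 2 (0.229) and with upper-quartile factors (0.204), where Atp5b turned to -0.04.

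Markers of other tissues in the samples were followed as well. Of 14 erythroid genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.231), with the globin gene Hbb-bs at 483 CPM in treated replicate 1 and 198 to 221 in the other 3 libraries. Globin copies share reads, so their single values are uncertain. Cardiac muscle genes passed as lower in 2 of 19 cases and as higher in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.613 with an estimated correlation), with Tcap and Myl7 at -1.09 and -1.05. The cardiac counts were 0 higher and 17 lower of 20 without treated replicate 2, 1 and 8 without treated replicate 1, and 0 and 0 without either normoxic replicate. Of 10 skeletal muscle genes Myh1 rose from 0.256 CPM, by 2.39 on the log2 scale and 1.62 without treated replicate 1, and Eno3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.396). None of 14 adipocyte genes passed (0 adjusted over the list alone; camera adjusted p = 0.378), and Lpl and Lipe were at 0.32 and 0.15. Without treated replicate 2 the erythroid list had adjusted p = 1.67e-06, as higher, and the adipocyte markers list 0.00319, as lower, while without treated replicate 1 their medians were -0.13 and 0.17.

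**Figure D3:**
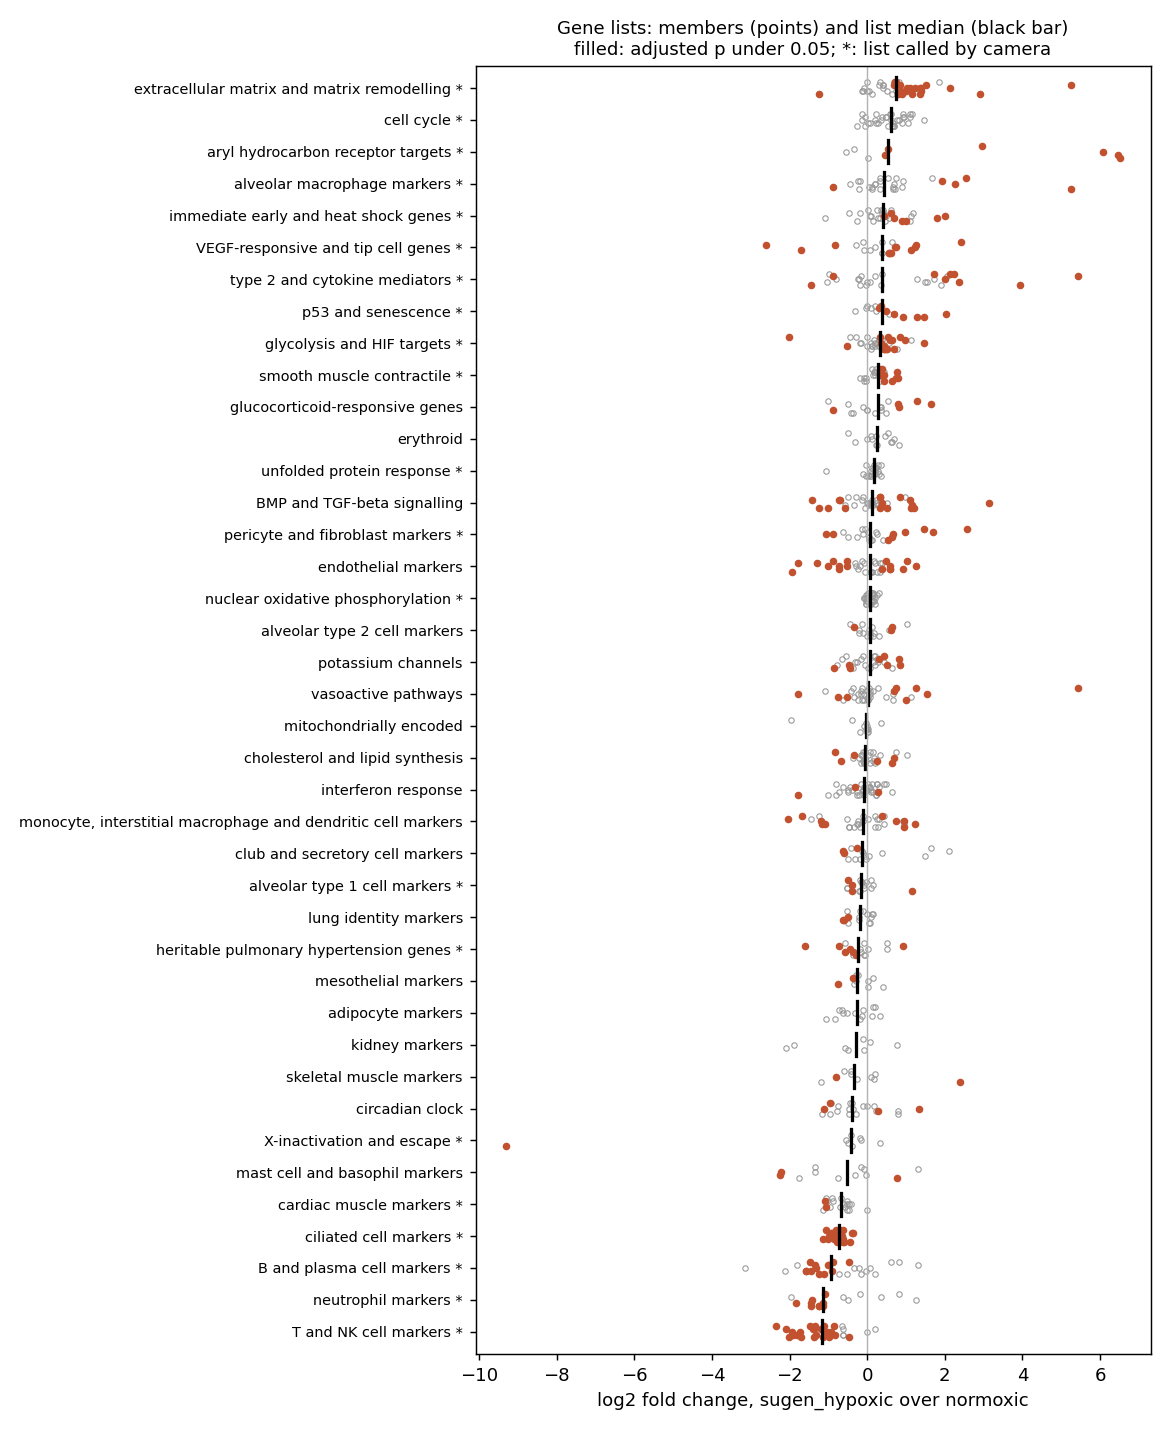
Log2 fold changes of Sugen-hypoxia over normoxia for the members of the 40 lists tested, with 1 point per gene, filled where edgeR's adjusted p was under 0.05, and a black bar at each list's median. Lists are ordered by median, and an asterisk marks the 21 that camera called with a preset correlation. The medians run from -1.16 for T and NK cell markers to 0.74 for extracellular matrix.

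In simulated data of this design with 200 changed genes 13.5% of calls were false, and the share among the 2163 genes was not measured. Scaling moved the balance of the calls, to 799 higher and 1424 lower with upper-quartile factors and to 765 and 1584 with library size alone.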

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

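The tests of pool sex in both patterns below, of other splits, of dilution and of clock phase were chosen after the values were seen, and the platelet test was fixed before its values were seen. Bootstrap intervals below describe the spread over genes and not the spread between pools. The tests of pool sex rest on a single mixed and a single all-female normoxic pool.

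Unmapped reads, which no comparison used, made up 7.35% of all reads on average in the Sugen-hypoxia libraries and 6.64% in the normoxic ones, with both treated pools above both normoxic pools. With 2 libraries against 2 the smallest two-sided p of an exact permutation test is 0.33.

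Reads on the strand opposite to a gene were also left out of the comparisons. In 25 genes with no annotated gene on that strand within 5000 bp such reads rose by edgeR's test, and in 43 they fell. Of the 25 genes, 17 rose on their own strand too, among them Cyp1b1, Lama1 and Vegfc. Cyp1b1 had 619 opposite-strand reads beside 170887 of its own. Among the genes whose opposite-strand reads rose or fell, 3 had more such reads than reads of their own. Whether these reads come from transcripts of the opposite strand was not tested.

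The first pattern weighed is the set of 2163 changed genes, since the treated pools were all male and the normoxic pools were not. If sex set the difference, the mixed normoxic pool, 2 of 3 male by label, would lie about 0.67 of the way from the all-female pool to the treated mean on the linear CPM scale, as Xist did at 0.7. Over the 105 autosomal genes called with that pool left out, its median position on that scale was 0.071 (95% bootstrap interval 0.044 to 0.117), which argues against sex as the cause for these genes as a set, while its part in the other genes and a treatment response that differs between the sexes stay open. The labels' split gave 2163 calls and the other 2 ways to halve the 4 libraries gave at most 0 (153 and 157 genes at unadjusted p under 0.05, edgeR), but with 1 of 3 splits as the smallest share, splits are too few to test chance. Treatment stays open as the biological explanation, and Sugen and hypoxia cannot be told apart since they were given together.

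The second pattern is the lower level of T and NK, B and neutrophil genes, whose 73 members had a median log2 fold change of -1.12. Dilution of all lung cells by RNA of other cells would lower alveolar markers alike. The median of 35 type 1 and type 2 markers was -0.083 (interval -0.179 to 0.09), which argues against such a common dilution. Ciliated cell and cardiac muscle markers fell too, with medians of -0.72 and -0.68, while those of endothelial and smooth muscle genes were 0.08 and 0.28. A dilution that spares alveolar cells is therefore not settled by the alveolar markers. The mixed normoxic pool had moved 0.097 of the way in relative CPM (interval 0.025 to 0.17), which argues against pool sex for these lists together. Neutrophil medians were -0.13 in the all-female and 0.13 in the mixed pool, opposite in direction to T and NK genes. From the all-female to the mixed pool Gzma fell from 20.5 to 14.5 CPM, Gzmb from 6.64 to 4.14 and Ncr1 from 4.68 to 3.27. A part of sex in single genes therefore stays open. Less blood in the lungs at harvest may remain a cause, since 15 platelet markers had a median of -0.563 with an interval of -0.746 to 0.038, but 12 of 14 erythroid genes were higher, with medians of 0.66 and -0.09 in the treated pools. The platelet median rests on normoxic replicate 2, since platelet medians were -0.44 and 0.44 in the normoxic pools and -0.49 and -0.51 in the treated pools, while T and NK medians were 0.07 and -0.07 against -1.12 and -1.24, and fewer such leukocytes in treated lungs stays open as a hypothesis.

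The third pattern is the opposite shift of clock genes, where 5 activators of the positive limb stood above 9 output genes by 1.73 on the log2 scale between groups. Of these 2 of 5 and 2 of 9 passed, and the lists had camera adjusted p = 0.00554 and 0.000328, lost at adjusted p = 0.443 and adjusted p = 0.458 with an estimated correlation. The clock list fixed beforehand was not called (camera adjusted p = 0.0855). These 2 lists were not among the 42 fixed beforehand, and the pattern was chosen after the values were seen. Their camera results therefore describe the shift and do not test it. Treated replicate 2 differed from treated replicate 1 in the same sense by 1.362, and the normoxic pools differed by -0.54. A different clock phase of single pools, such as another time of harvest, is consistent with that, and harvest times are not given in the sources used here. An effect of treatment on the clock also stays open.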

How the results depend on the processing

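Counts of changed genes (2163, with 1035 higher and 1128 lower) moved by over 1.5 times in several settings. Without a filter 3657 genes passed (1775 higher, 1882 lower). DESeq2 called 3254, of which 1651 were higher. A test against a 1.5-fold change called 177 (91 higher, 86 lower). With male fraction as a covariate, which leaves 1 residual degree of freedom, 11 genes passed (4 higher, 7 lower), 7 of them among the 2163. The lower ones included the 4 Y-linked genes, which were not among the 2163, and 1 gene of the X-inactivation list. The sign of the reported fit was kept in 2163 of the 2163 genes. All 2163 had been called with no overlap between the groups' libraries, which favours a kept sign, so this says little about the part of sex. Leaving out 1 library gave 25 to 5101 genes, 17 to 2663 higher and 8 to 2454 lower. The spread then comes from the other group's pair, and the treated pair differed more than 2-fold in 261 genes against 59 for the normoxic pair. RLE and upper-quartile factors, library size alone, a mean CPM filter, limma-voom, unstranded counts, autosomal genes alone, and haemoglobin and immunoglobulin genes left out gave 2153 to 2420 genes.

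Of 40 lists 21 passed camera, 17 to 26 did so in the other settings, but 0 passed with an estimated correlation and 0 with fry. The cell cycle list pointed lower with the male fraction (adjusted p = 0.915) and without treated replicate 2 (0.523), and had adjusted p = 1.8e-12 without treated replicate 1. Of 111 named genes that passed, 13 kept the call without normoxic replicate 1, 28 without normoxic replicate 2 and 6 with the male fraction. With that covariate Ddx3y, Kdm5d, Eif2s3y and Uty turned to -3.19, -4.57, -4.14 and -3.84, since a line in male fraction fits log2 values of a mixed pool poorly. Lrp2 (0.09) turned to -0.33 without treated replicate 2 and was at 0.41 without treated replicate 1, and the cause was not tested. No paired analysis was possible because replicate numbers follow the order of the records. Counting error is small for genes above 1 CPM, while genes under 0.1 CPM, such as Chodl in normoxia, rest on few reads.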

Other observations

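The lists in the next paragraph were written after the data were seen, and their tests are descriptions of these libraries.

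Lymphatic endothelial genes rose in 6 of 11 cases and fell in 1 (8 and 1 adjusted over the list alone). Prox1, the transcription factor of lymphatic identity, rose from 5.49 ± 0.406 to 16.4 ± 0.441 CPM (SD, n = 2), a log2 fold change of 1.58 ± 0.11, with Reln at 1.52 and Mmrn1 at 1.47, and camera gave adjusted p = 2.48e-05 (adjusted p = 0.352 with an estimated correlation). Vegfc, which drives lymphatic growth, rose beside them. Genes of retinoid metabolism fell in 4 of 14 cases and rose in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.381 with an estimated correlation). Lrat, which stores retinol as esters, fell 4.39-fold from 182 ± 54.2 CPM and Cyp26b1, which degrades retinoic acid, fell 6.85-fold (log2 fold change -2.15 without normoxic replicate 1 and -3.21 without normoxic replicate 2), while Aldh1a3, which makes it, rose 3.54-fold from 0.859 ± 0.0356 CPM. For Cyp26b1, at 238 CPM in the all-female and 115 CPM in the mixed normoxic pool, a part of pool sex stays open. Notch pathway genes were split, 3 of 15 higher and 4 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.632). The ligand Dll4, the target Hey1 and the receptor Notch2 fell by 2.60, 1.23 and 0.67, and the ligand Jag2 and the target Heyl rose by 1.14 and 0.94 on the log2 scale.

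The treated pools differed more than 2-fold from each other in 261 genes and the normoxic pools in 59. Each treated pool held 2 animals and each normoxic pool 3, and the part of pool size was not tested. Platelet markers went the other way, with medians of -0.44 and 0.44 in the normoxic pools and -0.49 and -0.51 in the treated pools. Medians against the normoxic mean were 0.13 and 0.78 for alveolar macrophage markers in treated replicates 1 and 2, -0.05 and 1.08 for cell cycle genes, 0.66 and -0.09 for erythroid genes, and -1.20 and 0.21 for adipocyte genes. By contrast they were -1.12 and -1.24 for T and NK genes and 0.34 and 0.30 for glycolysis and HIF targets.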
